A study of Rattus norvegicus with 2 samples.

How the data were processed

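Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for acetylated lysine 27 of histone H3 (H3K27ac) was carried out on sciatic nerves of Sprague Dawley rats at postnatal day 15. H3K27ac is a histone mark of active promoters and enhancers. The series holds 2 libraries, 1 from the H3K27ac immunoprecipitate and 1 from the matching input chromatin. Per the labels' protocols, nerves of several animals were combined before fixation, chromatin was sonicated, and libraries were made with a kit for ChIP samples. The length of the sonicated fragments limits how finely a peak edge can be placed.

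The deposited file is a single list of peaks with 3 columns, the chromosome, the start and the end. It gives no height, score, fold enrichment or p-value per peak. CASAVA 1.8.2, Bowtie and HOMER are named in the submitters' processing notes, without their roles or settings. The aligner settings, the peak caller's threshold, whether the input was subtracted and the genome build are not given in the sources used here. With 1 ChIP library, peaks were not called on pooled replicates. The read depth is unknown, since the list gives no counts, so no interval or detection limit based on reads is given. Peak starts are printed as the file's start plus 1, which takes the file to follow the BED convention. If it does not, starts are off by 1 base.

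Traces of the caller's settings were visible in the coordinates. No 2 peaks overlapped, neighbouring peaks were never closer than 500 bp, 5695 peaks were exactly 500 bp long, 1 was shorter (426 bp), and the next length above 500 bp was 625 bp. A length of 500 bp is therefore treated as the floor of the list.

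The only gene table at hand was of the assembly GRCr8. On 13 of the 21 chromosomes the last peak lay beyond the last gene of that table, by 63.8 Mb on chromosome 4, so the peak coordinates belong to another build. Coordinates were not converted, and no peak was assigned to a gene. The tests that had been laid out beforehand and that need gene positions or sequence were therefore not run. These were the share of peaks within 1 kb of transcription start sites, promoter and distal peaks of 14 gene lists (myelin, Schwann cell, other cell types of nerve, and control lists), the same lists at broad domains, and sequence motifs. Ranking by a peak score was not run either, since the file has none.

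The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peak density was the number of peaks divided by the span from the first to the last peak of a chromosome, with exact 95% Poisson intervals that cover counting error only. Because peaks cluster, the ratio of X to the autosomes was given a 95% interval from 2000 block bootstrap draws over blocks of 5 Mb. Spacing was compared with 1000 random placements of the same peaks on the same chromosomes, without overlap and at least 500 bp apart. The smallest two-sided p these placements can give is 0.002. Neighbours were peaks within 12.5 kb of each other, edge to edge. Domains were made by stitching peaks within the same 12.5 kb and ranked by the length covered by peaks, and the top 5% were called broad. Each chromosome's share of broad domains was compared with that of all other chromosomes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 21 chromosomes. This comparison was not laid out beforehand, when broad domains were to be tested by gene list. The median peak length on X was compared with that of all peaks by 100000 permutations of the peaks. Peak lengths were permuted within chromosomes 1000 times to test whether length went with the presence of a neighbour. Peaks and domains of 1 library are not replicates, so each p describes this list and says nothing of the spread between animals or libraries.

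The regions named were fixed by rule before the data were examined as the 10 longest peaks and the 10 domains with the most covered length. Chromosomes, peak-free stretches, windows of 1 Mb and the 3 largest domains of X were chosen after their values were seen, as were the comparisons of peak length between X and the autosomes and between peaks with and without a neighbour. Other settings fixed before the data were examined were peaks longer than the median (for the number, density and spacing of peaks), covered base pairs in place of peak numbers, neighbour distances of 5 and 25 kb, stitching within 5 kb, and the top 10% of domains. Settings added after seeing the data left out stretches over 5 Mb without a peak, peaks of 500 bp, or the densest X window, or, for broad domains, used single peaks in place of stitched domains or kept only peaks longer than the median. The steps were tested on simulated data. None of 20 lists placed at random, by the same rule as the placements used for comparison, was called clustered. Each of 20 lists with 20% of gaps shortened to within the neighbour distance was called. These lists do not test for calls that peak-free stretches alone could give. No call was made in 420 chromosome tests without a difference, in which domains were marked broad independently and at random. That simulation leaves out any link between peak density and domain size, so it does not test for calls that density alone could give. In the domain comparison, chromosome 5, with 1238 domains, was called in 20 of 20 simulations when given 2 times the odds. Chromosomes with fewer domains were not simulated in this way.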

Results

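H3K27ac was profiled by ChIP-seq in the sciatic nerve of rats at postnatal day 15, an age at which Schwann cells, the glia of peripheral nerve, are forming myelin. The series title places the experiment in an analysis of enhancers in peripheral nerve. Sciatic nerve is a mixed tissue of axons, Schwann cells, fibroblasts, blood vessels and immune cells, so the list of peaks describes the tissue and not a single cell type. The data were 1 H3K27ac library and 1 input library, without replicates, from which a single list of peaks was deposited. The comparisons below are between regions of the genome within that list, in the coordinates of the deposited file.

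The nerve carried 32996 H3K27ac peaks on the 20 autosomes and X, covering 73.8 Mb. The median peak was 1507 bp long, with quartiles at 730 and 2710 bp, and the mean was 2238 bp. Peaks over 5 kb made up 8.53% of the list (2815 peaks) and held 32.3% of the covered length. A further step up in length left 583 peaks over 10 kb, 87 over 20 kb and 10 over 40 kb. At the other end, 17.3% of peaks had the list's floor length of 500 bp.

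**Figure D1:**
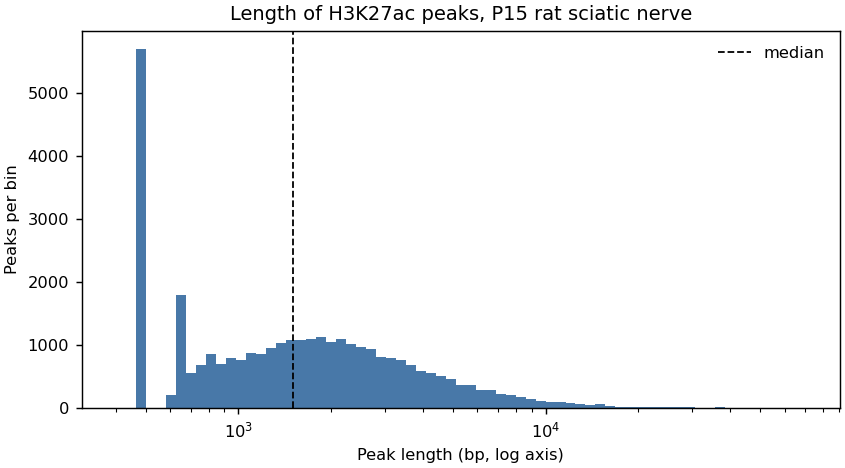
Histogram of the length of all 32996 H3K27ac peaks, with length in bp on a log axis and the number of peaks per bin on the vertical axis; the dashed line is the median of 1507 bp. The tall bar at the left holds the 5695 peaks of 500 bp, and the tail at the right reaches 69.0 kb.

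The longest single peak lay on chromosome 6 from 59203493 to 59272486 and spanned 69.0 kb. It was followed by peaks of 47.8 kb on chromosome 3 (11885522 to 11933360) and 46.0 kb on chromosome 14 (3645037 to 3690998). Chromosome 9 held a peak of 43.3 kb (80967916 to 81011200). Chromosome 1 held 2 of the 10 longest, one of 42.6 kb from 285164838 to 285207416 and one of 42.6 kb from 22421752 to 22464313. The remaining 4 were peaks of 42.3 kb on chromosome 12 (48599687 to 48641992), 41.2 kb on chromosome 7 (120414584 to 120455803), 41.1 kb on chromosome 5 (159566617 to 159607708) and 41.0 kb on chromosome 20 (9779391 to 9820390). Genes at these positions were not analysed here.

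Acetylated regions were unevenly spread over the chromosomes. Chromosome 10 had the highest density, 21.7 peaks per Mb (95% Poisson interval 20.8 to 22.6), followed by chromosome 12 with 20.2 (19.0 to 21.4) and chromosome 20 with 17.4 (16.3 to 18.5). The lowest densities were on X with 5.15 peaks per Mb (4.80 to 5.52), chromosome 4 with 7.62 (7.28 to 7.97) and chromosome 2 with 8.23 (7.90 to 8.57). The 20 autosomes averaged 12.54 peaks per Mb ± 3.64 (SD over chromosomes, n = 20). Peaks covered 5.40% of the span of chromosome 10, 1.62% of that of chromosome 4 and 0.886% of that of X. The place of chromosome 4 rested on 1 peak-free stretch of 66.0 Mb. With stretches over 5 Mb left out of every chromosome, chromosome 4 had 10.7 peaks per Mb and chromosome 2, at 9.31, was the sparsest autosome.

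**Figure D2:**
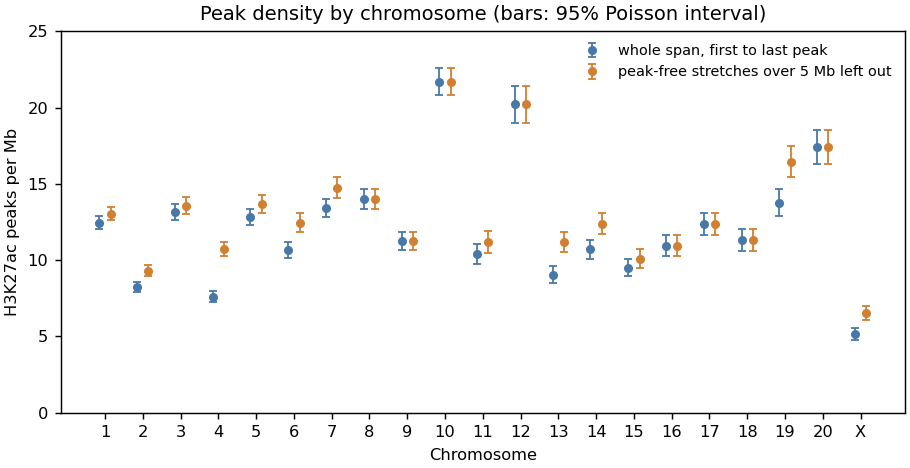
H3K27ac peaks per Mb (vertical axis) for each chromosome (horizontal axis), over the whole span from first to last peak in blue and with peak-free stretches over 5 Mb left out in orange; points are the densities of the 1 list and bars are exact 95% Poisson intervals. Chromosomes 10, 12 and 20 are highest, X is lowest by either measure, and chromosome 4 moves from 7.62 to 10.7 peaks per Mb.

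X had the fewest peaks per Mb and the shortest median peak of the 21 chromosomes. It carried 791 peaks, and its density was 0.437 times that of the autosomes together (95% block bootstrap interval 0.309 to 0.579). Measured as covered length, the ratio was 0.334 (0.227 to 0.458). Both intervals pool the autosomal blocks and leave out the spread between chromosomes. Chromosome 10 lay farther above the mean of the autosomal densities than X lay below it. X ranked last of 21 chromosomes, for which a two-sided exact rank test gives p = 0.0952, the smallest a single chromosome can reach. The median X peak was 1231 bp long against 1515 bp on the autosomes, a difference of -284 bp (95% bootstrap interval -365 to -183), and the permutation test gave p = 1e-05, the smallest that 100000 permutations allow. Peaks over 5 kb were 4.17% of X peaks (33 peaks) and 8.64% of autosomal peaks, with an odds ratio of 0.460 and p = 1.62e-06 by Fisher's exact test, two-sided. Peaks of the floor length were 21.6% of X peaks and 17.2% of autosomal peaks (odds ratio 1.33, p = 0.00140 by the same exact test). These length tests and the interval of the median treat peaks as independent. Lengths of neighbouring peaks were related, as given below, so the certainty can be overstated. The spread between chromosomes is also left out: autosomal medians ran from 1393 bp on chromosome 17 to 1605 bp on chromosome 7, all above that of X. The sex of the animals was not taken into account, since the labels do not give it.

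Peaks were unevenly spread along X. Of 155 windows of 1 Mb on X, 52 held no peak, and the median window held 2 peaks. The window from 115 to 116 Mb alone held 55 peaks, 6.95% of all X peaks, and only 10 windows in the genome held more. The next densest X windows, at 69 to 70 Mb and 72 to 73 Mb, held 36 and 30 peaks. Without the peaks of the 115 to 116 Mb window, the ratio of X to autosomal density was 0.407.

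**Figure D3:**
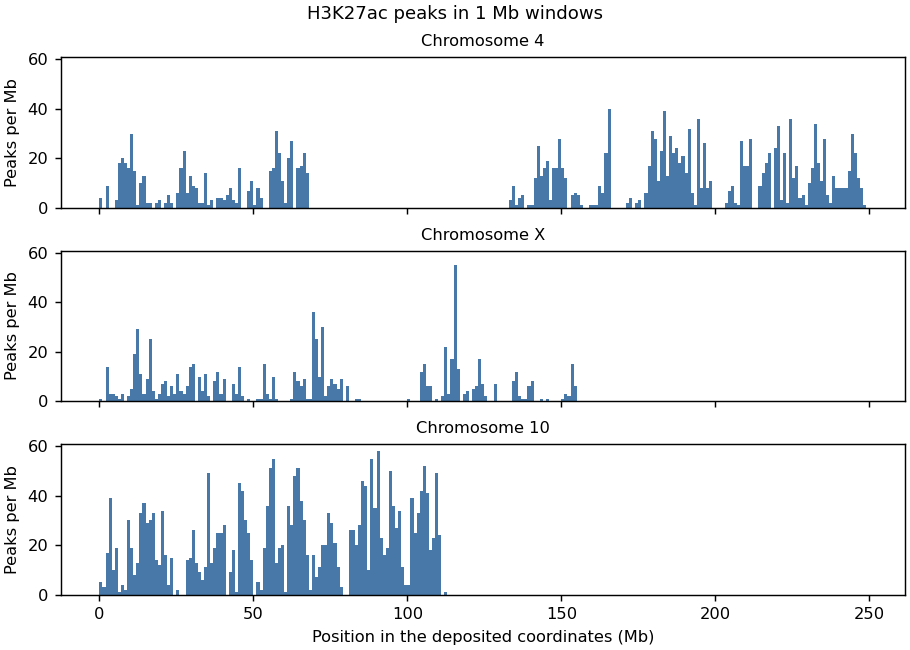
H3K27ac peaks in consecutive 1 Mb windows (vertical axis, peaks per Mb) along chromosomes 4, X and 10 in the deposited coordinates (horizontal axis, Mb). Chromosome 4 has no peak over 66.0 Mb, X has a single tall window of 55 peaks at 115 to 116 Mb, and chromosome 10 is filled along most of its length.

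Peaks occurred in clusters. Of all peaks, 63.4% had another peak within the neighbour distance fixed beforehand and used for stitching, as given with the processing, against a mean of 26.4% when the same peaks were placed at random on their chromosomes (range 25.4 to 27.6% over 1000 placements, two-sided permutation p = 0.002, the smallest these placements can give). Within 5 kb the observed share was 41.0% and the random share 10.96%, and within 25 kb they were 78.2% and 46.0%. The placements used the whole span, including long stretches without a peak. With stretches over 5 Mb left out, the random share at the stitching distance was 28.0%, while shorter peak-free stretches stayed in. How the caller separates nearby peaks is unknown and may also act on the observed shares. The median distance between neighbouring peaks was 16.8 kb, compared with 55.8 kb at random. Across the genome, the densest 10% of the 2909 windows of 1 Mb held 34.9% of the peaks, while 607 windows (20.9%) held none. The densest windows were on chromosome 7 from 12 to 13 Mb, with 77 peaks covering 254 kb, and on chromosome 1 from 184 to 185 Mb, with 71 peaks covering 206 kb. The adjoining window of chromosome 7, from 11 to 12 Mb, followed with 65 peaks.

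Clustered peaks were also longer. The 20922 peaks with a neighbour within the stitching distance had a median length of 1692 bp (quartiles 793 and 3124 bp), and the 12074 isolated peaks had a median of 1269 bp (649 and 2141 bp). The difference of 423 bp exceeded that of every within-chromosome permutation of the lengths (permutation p = 0.001, the smallest 1000 permutations allow). Peaks over 5 kb were 11.3% of clustered and 3.68% of isolated peaks. Among the 14260 neighbouring pairs, the lengths of the 2 peaks were weakly related across peaks (Spearman's rho 0.107, highest permuted value 0.031, permutation p = 0.001). Peaks are not independent replicates, and a caller's rule for joining nearby signal into 1 peak may also act on length, which was not tested.

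Stitching peaks within that distance gave 18736 domains, of which 12074 (64.4%) were single peaks and the most populous held 18 peaks. The 937 broad domains, the top 5% by covered length, each had at least 14.1 kb covered by peaks. Their median was 21.3 kb of covered length in 6 peaks over a span of 42.4 kb. They held 32.4% of all covered length and 16.8% of the peaks. In 200 random placements the top 5% held 23.3% on average and at most 23.5%, but out of more domains, 28279 on average. The longest 5% of single peaks, without stitching, held 23.4%.

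The largest domain lay on chromosome 1 from 274473001 to 274606971, where 9 peaks covered 114.5 kb, or 85.5% of the span. A domain on chromosome 14 (3604281 to 3724672) had 104.1 kb covered in 7 peaks and contained the peak of 46.0 kb described above. Chromosome 1 held 2 further domains over 100 kb, one of 15 peaks covering 102.2 kb (227976877 to 228172314) and one of 16 peaks covering 101.4 kb (211655796 to 211811527). Next came domains on chromosome 10 (105855017 to 105990132, 99.7 kb in 13 peaks) and chromosome 17 (724094 to 860378, 98.4 kb in 13 peaks). The other 4 of the 10 largest were 2 on chromosome 3, covering 86.0 kb (35089952 to 35200343) and 80.9 kb (168689684 to 168810443), 1 on chromosome 19 covering 85.8 kb (41673300 to 41781200), and 1 on chromosome 9 covering 83.7 kb (80967916 to 81086019). None of the 200 random placements gave a domain with more than 82.3 kb covered.

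**Figure D4:**
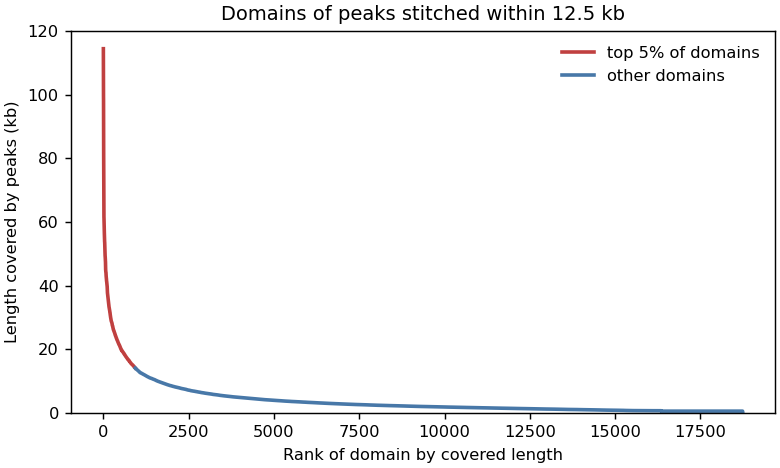
Length covered by peaks (vertical axis, kb) of each of the 18736 domains, ordered by rank (horizontal axis), with the 937 domains of the top 5% in red and the others in blue. The curve falls from 114.5 kb at the first domain to 14.1 kb at the last of the top 5%.

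Broad domains were not shared evenly among the chromosomes. On chromosome 10, 7.70% of domains were broad (95 of 1233) against 4.81% elsewhere, an odds ratio of 1.65 with an adjusted p of 0.000523 by Fisher's exact test. Chromosome 3 also lay above the rest (6.72%, odds ratio 1.41, adjusted p = 0.0232 by the same exact test). X had the lowest share, 2.08% (11 of 528, odds ratio 0.397, adjusted p = 0.00808 by the exact test), and chromosomes 4, 9 and 2 were below the rest with odds ratios of 0.595, 0.618 and 0.701. The other 15 chromosomes did not pass the threshold, among them chromosome 20 with 7.30% (odds ratio 1.52, adjusted p = 0.0635 by the exact test). Only chromosome 10 passed under each alternative. These tests treat domains as independent and leave out the spread between chromosomes, so the certainty can be overstated. The comparison did not adjust for peak density. Stitching within a fixed distance joins more peaks where they lie closer, so these shares can in part restate density. As single peaks, without stitching, chromosome 10 had an odds ratio of 1.29 and X of 0.337. Among peaks longer than the median, a setting chosen after seeing the data, X had an odds ratio of 0.305 with an adjusted p of 0.0542 by the exact test, and without stitching chromosomes 2, 3, 4 and 9 no longer passed, with odds ratios between 0.744 and 1.14.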

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

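Most values kept their direction. Chromosome calls of broad domains held less well. With each of the 6 called chromosomes counted once per alternative setting, 12 calls, on chromosomes 2, 3, 4, 9 and X, lost the threshold. Keeping only peaks longer than the median left 16489 peaks, fewer by construction, and left 1 chromosome (10) in place of 6 with a differing share of broad domains; fewer domains were tested there, 11027 against 18736, and the odds ratios of chromosomes 2, 4, 9 and X were then 0.714, 0.526, 0.593 and 0.305, against 0.701, 0.595, 0.618 and 0.397 among all peaks, and that of chromosome 3 was 1.20 against 1.41. This setting for domains was chosen after seeing the data. Under stitching within 5 kb, the top 10% and single peaks, the number of differing chromosomes was 5, 5 and 4, not always with the same members: chromosome 11 passed within 5 kb (odds ratio 0.524) and, as single peaks, chromosomes 11 (0.517) and 1 (1.33) did. Chromosome 9 passed under none of these settings and chromosome 4 only under the top 10%, and no odds ratio of chromosomes 2, 3, 4, 9, 10, 20 or X changed direction. The ratio of X to autosomal density ranged from 0.334 (covered length) to 0.506 (without stretches over 5 Mb), and clustering at the stitching distance from 2.26 times the random share without those stretches to 3.58 times for longer peaks. Restricting to placed chromosomes or merging overlapping peaks moved nothing, since every peak is placed and none overlap. The settings for promoters, gene lists and motifs, and the ranking of domains by score, were not run. With 1 library there is no leave-one-out value, and without read counts the depth that limits weak peaks is unknown.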

Other observations

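The tests below were chosen after the patterns had been seen. Large parts of the genome carried no peak: 443 stretches over 1 Mb added up to 1050 Mb, 36.4% of the span, where random placement gave 5.82 such stretches on average. Stretches over 5 Mb numbered 27 on 13 chromosomes, with a highest count of 0 in the random placements. After chromosome 4, the longest were 20.5 Mb on chromosome 2 (20334635 to 40818422), 16.4 Mb on X (84279087 to 100705286), 11.7 Mb on chromosome 19 (11862659 to 23588435) and 11.6 Mb on chromosome 13 (2806015 to 14359373).

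Although broad domains were fewer on X, 11 of its 528 domains were among the top 5% of the genome. The largest X domain, from 116307461 to 116368186, had 53.8 kb covered in 4 peaks, close to the densest X window. Next in rank came a domain from 115145864 to 115221329, with 36.9 kb covered in 11 peaks, and one from 70008641 to 70103287, with 32.3 kb covered in 16 peaks. Across the list, 50 domains covered more than 50 kb.

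The stretch of chromosome 4 from 67355849 to 133355985, 66.0 Mb without a peak, was over 3 times as long as any other. Uniform random spacing is argued against, since the longest stretch in 1000 random placements was 2.70 Mb. Every stretch over 5 Mb exceeds that length by definition, so the placements do not set this stretch apart from the others. The deposited coordinates of chromosome 4 run 63.8 Mb past the last gene of the GRCr8 table, more than on any other chromosome, and that excess is close to the length of the stretch, so a candidate explanation is that this build holds coordinates there to which reads could not be assigned. Over the 21 chromosomes, the excess went with the summed length of stretches over 5 Mb (Pearson's r 0.844, permutation p = 0.00063; Spearman's rho 0.555, permutation p = 0.0108), but without chromosomes 2 and 4 r was 0.300 (permutation p = 0.211) and rho 0.393 (permutation p = 0.0959), so the relation no longer passed the threshold, while both coefficients stayed positive. Where on chromosome 4 the excess lies, inside the stretch or elsewhere, was not tested, and no biological explanation was tested.

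For the fewer and shorter peaks on X, peak-free stretches over 5 Mb do not account for the whole difference in density. Without them the ratio to the autosomes was 0.506 (95% block bootstrap interval 0.378 to 0.651). Shorter peak-free stretches stayed in, so whether they account for the rest was not tested. Whether a lower signal on X, from fewer copies per cell or from less acetylation, removed or shortened peaks stays open. The ratio was 0.355 among peaks longer than 1507 bp and 0.527 among the others, a difference of -0.172 (-0.255 to -0.077), but this split by length restates that X peaks were shorter and decides nothing. Neither the input coverage nor the sex of the animals was analysed here. A lower content of genes or a higher content of repeats on X also stays open, as untested.

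The rows of the file are not in genomic order, and length goes with the row number, though not steadily. In consecutive blocks of about 3300 rows the median rose from 1805 bp in the first to 2078 bp in the next, then fell to 1149 bp in the last. The first 1000 rows held 29.8% peaks of the floor length, against 16.9% in the other rows. Spearman's rho of row number and length was -0.175, outside every one of 1000 permutations (largest absolute value 0.019). A candidate explanation is that the rows keep the order of a peak measure that the file no longer holds. X peaks were more frequent at the start, 118 of the first 3300 against 60 of the last 3300 (odds ratio 2.00, p = 1.26e-05 by Fisher's exact test, two-sided). What the order stands for is unknown, so early rows cannot be read as strong peaks.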
